A study of Homo sapiens with 6 samples.

How the data were processed

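The study measured where RNA polymerase II and histone marks lie on human promoters by chromatin immunoprecipitation followed by hybridisation to a promoter tiling array. There were 6 arrays. In THP1 cells, a human monocytic leukaemia line, 1 array each was made for RNA polymerase II (Pol II), for its form phosphorylated on serine 5 of the C-terminal domain (Ser5P), and for histone H3 acetylated on lysine 9 (H3K9Ac). In primary monocytes, H3 trimethylated on lysine 4 (H3K4Me3) was measured in 3 volunteers, 1 array each. Groups were taken from the sample titles.

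Per the labels, immunoprecipitated DNA carried Cy5 and the control carried Cy3 on the same array. The sample labels name the control channel an IgG control for THP1 cells and a control without antibody for monocytes, while the extraction protocol speaks of a control without antibody, so the kind of THP1 control is in doubt. The deposited intensity of each spot was, per the file headers, extracted with NimbleScan, version 2.5.26 for the THP1 arrays and 2.6.0.0 for the monocyte arrays, and no background subtraction or normalisation is named there. The deposited ratio files hold log2 ratios of Cy5 over Cy3 minus the array's Tukey biweight mean, per the file headers. Recomputing these log2 values from the intensities matched the authors' values within 0.005 after alignment of the medians. The authors' series table held the same log2 values as the ratio files, with a largest difference of 0 over 713286 probes and column medians from -0.04 to 0.02, so its scale, centring and direction were known. The design names give hg18 as the build and RefSeq promoters as the target. The THP1 and monocyte arrays carry different issues of this design with the same probes.

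The mark, the cells, the labelled kind of control, the issue of the design and the software version all changed together between THP1 cells and monocytes. The 6 arrays lay on 4 slides. Pol II and Ser5P shared slide 1, H3K9Ac was on slide 2, volunteer 1 was on slide 3, and volunteers 2 and 3 were on slide 4.

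The array tiled 19995 regions, mostly 4000 bp long. The value of a region on an array was the mean over its probes of log2(Cy5 / Cy3), minus the array's median over all 713286 probes. No loess or quantile step was applied, because many promoters may carry signal. A value of 0 is therefore the median probe of the array and not an absence of the mark. Regions needed at least 8 probes, and only the 22 autosomes were used, which left 18585 regions with a median of 36 probes. Regions on the sex chromosomes, 959 in number, were not examined, because the monocytes come from people.

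Monocyte region values were tested against 0 with limma 3.58.1 in R 4.3.3, using an intercept-only fit, moderated variances with a trend on the mean value, and Benjamini-Hochberg adjustment at 0.05, two-sided. The estimated prior degrees of freedom were infinite, beside 2 residual ones. Each region was therefore tested with the variance that the trend gives for its mean value, and its own spread between volunteers did not enter the test. A t-test per region, with its own variance, was added after this was seen. Pairs of marks were compared by Pearson's r and Spearman's rho across regions and by the percent of top 10% regions shared, with exact (Clopper-Pearson) 95% binomial intervals that cover counting error only. Regions are not independent replicates, so no p-value was given for these. Intervals of r came from 10000 draws of the 22 chromosomes with replacement. Position differences had intervals from 1000 draws of regions. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 served for the rest.

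The limma step was tested on simulated data for the monocyte comparison, with 18585 regions, of which 200 were shifted. Noise was normal and independent between regions, with the pooled spread that the same fit gave and not each region's own. The step recovered 12% of 50 regions shifted by 0.1 on the log2 scale, 82% at 0.2, 100% at 0.4 and 100% at 0.8. Of its calls 4.55% were false. These rates hold for that setting and do not check the calls on the real arrays. A simulated pair of arrays with a true r of 0.5 gave 0.500 and shared 31.8% of top regions, against 8.77% for a pair with a true r of 0. A position difference simulated at 0.2 was estimated at 0.206.

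The files pair regions with hg18 positions and not with genes. The gene table used here is of another build, and coordinates were not converted. Gene names were therefore not given, and the planned tests of gene lists were not run. The rule for regions given by position was fixed before the data were examined: at most 2 per direction, taken as the highest monocyte means among regions past the test and in the top 10% of each of the 3 arrays, the highest values of each THP1 array, and the largest rank differences between Pol II and Ser5P and between monocyte H3K4Me3 and THP1 H3K9Ac. Start and end are given as in the files.

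The files also hold 3000 random-sequence probes per array, which show the brightness of spots without a genomic target. The precision of each value is limited by the number of arrays. Between 16.6% and 34.6% of probes per array were brighter than the 95th percentile of the random probes in at least 1 channel.

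Alternatives planned before the data were examined were the authors' ratios, normexp background correction with an offset of 50, loess within arrays, quantile normalisation between arrays, the median over probes, the best run of 8 neighbouring probes, no probe minimum, removal of probes dim on all 6 arrays, removal of the trend on the control signal with a loess span of 0.3, limma's treat against 0.5, no variance trend, Spearman's rho, top 5% and 20% lists, and each monocyte array left out. Single-match probes, chromosome 1 left out, the t-test per region and averaging the arrays of a slide were added after the data were seen. The comparisons by place within a region, by 5 Mb window, by chromosome and by number of genome matches were also chosen after looking at the data. That exploration also looked at bins of other widths on chromosome 1, at neighbouring regions and at classes of probe length. The probe count of genome matches came from the deposited ratio files.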

Results

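Promoter occupancy was profiled on 6 arrays of 713286 probes. THP1 cells gave 1 array each for Pol II, Ser5P and H3K9Ac, so these have no replicate check, and monocytes of 3 volunteers gave 1 array each for H3K4Me3. Ser5P is the form of the polymerase found mainly at the start of transcription, and H3K9Ac and H3K4Me3 are histone marks typical of active promoters. The median probe intensity lay between 325 and 1622 in the immunoprecipitated channel and between 439 and 1209 in the control channel. Random-sequence probes had median log2 ratios from -0.22 on the Pol II array to -0.88 on the H3K9Ac array, relative to the array median.

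The spread of region values differed between marks. Its SD over the 18585 autosomal regions was 0.43 for Pol II, 0.55 for Ser5P and 0.49 for H3K9Ac on the log2 scale. For monocyte H3K4Me3 it was 0.31 ± 0.02 (SD, n = 3). The 90th percentile of regions lay at 0.91 for Pol II, 0.88 for Ser5P and 0.78 for H3K9Ac, and at 0.52 ± 0.04 (SD, n = 3) for H3K4Me3. Antibodies and controls differed between the arrays, so pairs of marks were compared by rank and correlation. Heights and spreads are given to describe each array, and their differences between marks were not tested.

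**Figure D1:**
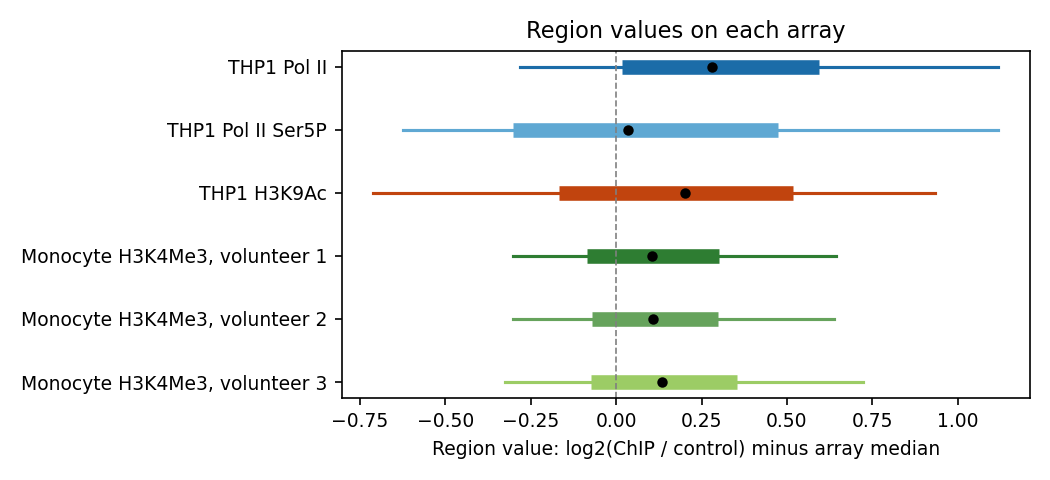
Distribution of region values over 18585 autosomal regions on each of the 6 arrays, with log2(ChIP / control) minus the array median on the x axis. Points are medians, thick bars span the 25th to 75th percentile and thin bars the 5th to 95th. The monocyte arrays have the narrowest range, with SDs of 0.30, 0.30 and 0.33.

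H3K4Me3 in monocytes was examined to ask which promoters lie above or below the array's median probe for this mark. Such a call does not show the mark to be present or absent. Chromosome means also followed mean probe length (r = 0.680, given below), so the ranking of regions may not reflect the mark alone. Of 18585 regions, 10472 lay above the array median and 4768 below it, and 3345 did not pass the test (limma, Benjamini-Hochberg adjusted, 3 arrays). The regions above the median included 1975 with a mean over 0.5 and 255 with a mean over 1 on the log2 scale. The 3 volunteers ranked regions alike. Region values correlated across regions at r = 0.977 between volunteers 1 and 3, 0.940 between volunteers 1 and 2, and 0.947 between volunteers 2 and 3, who shared a slide. The 3 arrays had the same sign in 86.7% of regions, against 32.3% for independent arrays with the same shares of positive regions, and 1354 regions were in the top 10% on all 3 arrays. The SD between volunteers had a median of 0.06 per region, against an SD of 0.31 between region means. Without variance shared between regions, which leaves 2 degrees of freedom for each, the same fit called 7139 regions above and 2851 below. The split of the calls depended on how probes were averaged. With the median over probes, 6330 regions lay above and 5843 below, which is 52.0% above against 68.7% with the mean. With the best 8 neighbouring probes 15972 lay above and 800 below. Against a log2 ratio of 0.5, treat called 941 regions above and 0 below.

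The highest H3K4Me3 region in monocytes lay on chromosome 3 from 75916145 to 75920145 (hg18). Its mean log2 ratio was 2.41 ± 0.07 (SD, n = 3), and in THP1 cells it was at the 99.7 percentile of Pol II regions, the 96.6 percentile for Ser5P and the 34.2 percentile for H3K9Ac. The next lay on chromosome 13 from 56622995 to 56626995, at 2.11 ± 0.38 (SD, n = 3). Of the probes in these regions, 52.0% and 100% matched more than 1 place in the genome. A further pair was chosen after the values were seen, as the highest regions whose probes all matched 1 place. They lay on chromosome 9 from 114858017 to 114862017, at 1.91 ± 0.15 (SD, n = 3), and on chromosome 10 from 127571897 to 127575897, at 1.69 ± 0.06 (SD, n = 3). In THP1 cells the regions on chromosomes 13, 9 and 10 were at the 6.38, 1.08 and 14.7 percentiles for H3K9Ac. For Pol II they were at the 88.8, 62.4 and 83.9 percentiles, and for Ser5P at the 77.9, 38.5 and 72.0 percentiles. The lowest regions lay on chromosome 3 from 46693103 to 46697103, at -0.54 ± 0.03 (SD, n = 3), and on chromosome 11 from 1894174 to 1898174, at -0.54 ± 0.07 (SD, n = 3). The adjusted p of these 6 regions was at most 2.42e-44 by limma, which here rested on the pooled spread of all regions and not on that of the region.

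Regions that matched several genome places were common among the strongest. Regions in which over 50% of probes had more than 1 match made up 4.86% of all regions. They made up 17.9% of the 1354 regions at the top in all 3 volunteers. Their share was 12.6% of the Pol II top 10%, 9.52% for Ser5P and 10.3% for H3K9Ac.

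Pol II and Ser5P were compared in THP1 cells to set the total polymerase beside its initiating form. Promoters with much Pol II also had much Ser5P. The correlation across regions was r = 0.663 (95% interval over chromosomes 0.637 to 0.684) and rho = 0.645. Of the top 10% of Pol II regions, 48.6% were also in the top 10% of Ser5P (95% exact interval 46.3 to 50.9), against 10% by chance. Both values were lower with dim probes left out, at r = 0.520 and 37.0% shared. The region on chromosome 1 from 40275641 to 40279641 was the highest on both arrays, with log2 ratios of 2.99 for Pol II and 3.01 for Ser5P. The next for Pol II lay on chromosome 1 from 40743819 to 40747819 at 2.88, and the next for Ser5P on chromosome 6 from 31811520 to 31816552 at 2.99. At some promoters the ranks of the 2 forms lay far apart on these single arrays. The region on chromosome 5 from 137923898 to 137927898 was at 1.54 for Ser5P and -0.54 for Pol II, and that on chromosome 11 from 64283963 to 64287963 was at the 98.3 percentile of Ser5P regions and the 3.27 percentile of Pol II regions. In the other direction, the region on chromosome 1 from 199445192 to 199449192 was at 1.17 for Pol II and -0.86 for Ser5P, and 52.6% of its probes had more than 1 match. The region on chromosome 14 from 94173614 to 94177614 was at 1.16 and -0.83.

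H3K9Ac rose with both forms of the polymerase, and r was higher with Ser5P than with total Pol II on these single arrays. Between Ser5P and H3K9Ac r was 0.668 (95% interval over chromosomes 0.643 to 0.689) and rho 0.678, and 47.4% of top regions were shared (95% exact interval 45.2 to 49.7). Between Pol II and H3K9Ac r was 0.510 (0.480 to 0.536) and rho 0.509, and 35.3% were shared (33.2 to 37.6). The difference between the pairs was not tested over replicates, since each mark had 1 array. Pol II and Ser5P lay on slide 1 and H3K9Ac on slide 2. The Pol II array was also dimmer, with a median immunoprecipitated intensity of 325 against 515 for Ser5P. Whether this lowered its r was not tested. The highest H3K9Ac region lay on chromosome 1 from 40926628 to 40933720 at 2.16. It was followed by the region from 40275641 that led both polymerase arrays, at 2.15. In all, 486 regions were in the top 10% of all 3 THP1 arrays, or 2.62% against 0.1% for independent lists. The lists share cells and probes, so the excess may not reflect common occupancy alone. In the 486 regions 20.4% of probes had several genome matches, against 5.34% in regions at the top of no THP1 array. With dim probes left out, r between Pol II and H3K9Ac was 0.337 and the shared part 23.0%. For Ser5P and H3K9Ac these were 0.617 and 37.7%.

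The labels do not say whether the THP1 arrays shared 1 IgG preparation. The covariance of region values was 0.158 for Pol II with Ser5P, 0.109 for Pol II with H3K9Ac and 0.182 for Ser5P with H3K9Ac. Unchanged arrays made from the control channels alone, with the third array's control as the common one, gave covariances of 0.006, 0.001 and 0.007. Their r was 0.640, 0.137 and 0.673, against 0.663, 0.510 and 0.668 observed. This r is raised by construction, since the same control channel is subtracted in both arrays of a pair. It therefore sets no level for the observed r, and r alone decides nothing here. With H3K9Ac the control channels alone gave the same order of r, Ser5P above Pol II. By covariance they gave far less than was observed. Part of the excess may still come from a preparation common to the arrays.

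H3K4Me3 in monocytes was set beside the THP1 marks to ask how far active promoters coincide in the 2 cell types. The overlap was above chance. It was below that within THP1 cells with all probes averaged, but this order depended on the probes used. With Pol II the monocyte mean gave r = 0.364 and rho = 0.364, and the r of single volunteers was 0.359 ± 0.032 (SD, n = 3). With H3K9Ac it gave r = 0.216 and rho = 0.287, with 0.213 ± 0.040 (SD, n = 3) over volunteers. Top regions were shared at 26.8% with Pol II (95% exact interval 24.8 to 28.9), 26.4% with Ser5P (24.4 to 28.5) and 25.7% with H3K9Ac (23.7 to 27.8). Among the 1354 regions at the top in all 3 volunteers, 170 were also at the top on all 3 THP1 arrays, or 12.6% against 2.62% of all regions. The 486 regions at the top of all THP1 arrays had a monocyte H3K4Me3 mean of 0.50 ± 0.06 (SD, n = 3), against 0.09 ± 0.01 in the 14965 regions at the top of none. The sets differ in their probes: 20.4% of probes per region had several genome matches in the first and 5.34% in the second, and 71.4% and 87.0% of regions were 4000 bp long. A comparison chosen after these values were seen kept 4000 bp regions without such probes. The means were then 0.44 ± 0.06 in 192 regions and 0.05 ± 0.01 in 9350 (SD, n = 3). Mark, cells, labelled control and design issue differed together, so no test of cell type was made. With H3K9Ac, r was 0.362 over the best 8 neighbouring probes and 0.331 without dim probes. Over the best 8 probes, monocytes and H3K9Ac shared 38.4% of top regions against 34.6% for Pol II and H3K9Ac in THP1 cells. Without dim probes these shares were 28.1% and 23.0%, and r was 0.369 for monocytes with Pol II against 0.337 for Pol II with H3K9Ac.

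**Figure D2:**
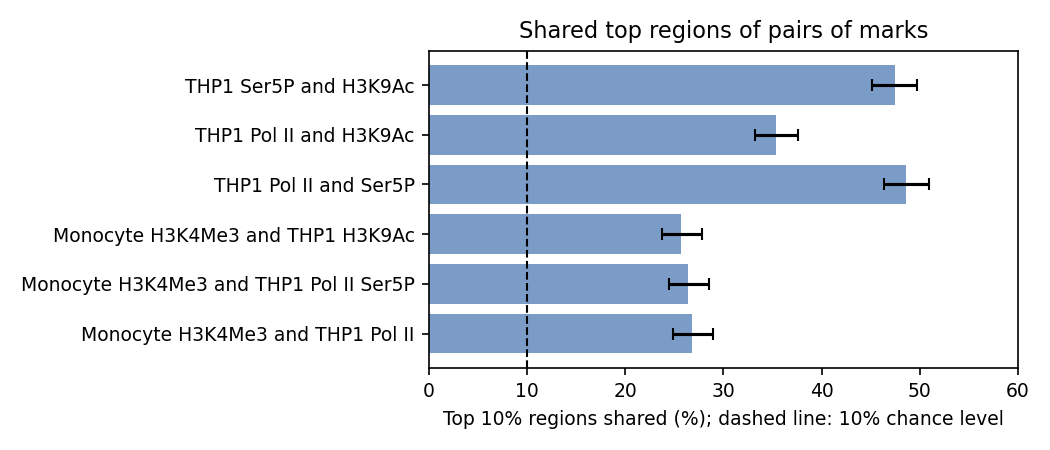
Percent of the top 10% of regions shared by pairs of marks (x axis), with 95% exact binomial intervals and a dashed line at the 10% chance level. Pairs within THP1 cells lie between 35.3% and 48.6%, and pairs with the mean of 3 monocyte arrays between 25.7% and 26.8%.

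At some promoters H3K4Me3 in monocytes and H3K9Ac in THP1 cells ranked far apart, which compares different marks and does not show a mark to be absent. The region on chromosome 19 from 63176914 to 63180914 had a monocyte H3K4Me3 mean of 1.63 ± 0.08 (SD, n = 3) and a THP1 H3K9Ac value of -1.03. The region on chromosome 19 from 49643705 to 49647705 was at 1.37 ± 0.14 (SD, n = 3) and -1.01. In the other direction, the region on chromosome 1 from 41259174 to 41263174 was at 1.22 for H3K9Ac and -0.43 ± 0.02 (SD, n = 3) for H3K4Me3, and that from 42977712 to 42981712 at 1.27 and -0.32 ± 0.07 (SD, n = 3). Both lie in the window from 40 to 45 Mb described below, where 68 regions averaged 1.01 for H3K9Ac. Much of their H3K9Ac height may thus be common to that window and not particular to these promoters.

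Within the 4000 bp regions the polymerase and the histone marks differed in their mean profiles. Means were compared between probes 600 to 1100 bp from the nearest region edge and probes 1500 to 2000 bp from it, over 15645 regions. Pol II was at 0.39 in the belt from 600 to 1100 bp and 0.21 in the middle, a difference of 0.18 (95% interval over regions 0.17 to 0.20). Ser5P was at 0.13 and 0.00, a difference of 0.13 (0.12 to 0.14). H3K9Ac was at -0.04 and 0.26, a difference of -0.30 (-0.31 to -0.29). H3K4Me3 was at 0.01 ± 0.01 and 0.20 ± 0.04, a difference of -0.18 ± 0.04 (SD, n = 3), with the same sign in 3 of 3 volunteers. The differences were larger among strongly occupied promoters. In the top 10% of Pol II regions they were 0.29 for Pol II, -0.53 for H3K9Ac and -0.32 ± 0.07 (SD, n = 3) for H3K4Me3. In the lower 50% they were 0.11, -0.18 and -0.12 ± 0.03. With loess within arrays the Pol II difference was 0.08 and the Ser5P difference 0.07. Single regions varied: values were higher in the belt than in the middle in 60.2% of regions for Pol II and 57.3% for Ser5P. For H3K9Ac this held in 31.9% of regions, and for H3K4Me3 in 37.0%, 36.8% and 31.9%. The low histone values were a local dip. In the outermost 100 bp H3K9Ac was at 0.20 and H3K4Me3 at 0.22 ± 0.03 (SD, n = 3). The polymerase arrays also had a low point within the belt, which was shallower and was not tested. Pol II was at 0.39, 0.35 and 0.39 in the bins from 600, 800 and 1000 bp. Ser5P was at 0.10, 0.08 and 0.15 in the bins from 600, 700 and 1000 bp. The bin from 1000 bp was the highest for Ser5P, and H3K9Ac had risen to 0.05 there.

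**Figure D3:**
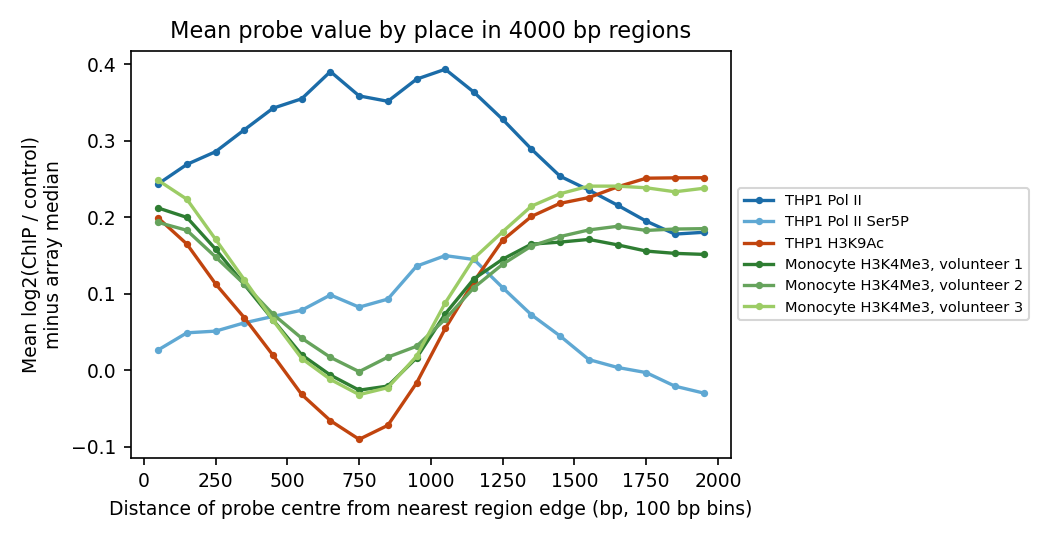
Mean log2(ChIP / control) minus the array median (y axis) by distance of the probe centre from the nearest edge of 4000 bp regions, in 100 bp bins (x axis), with 1 line per array. The H3K9Ac line falls to -0.09 and the monocyte lines to between -0.03 and 0.00 in the bin from 700 bp, where Pol II is at 0.36. In the outermost bin H3K9Ac is at 0.20 and the monocyte lines are between 0.19 and 0.25.

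Along the chromosomes, some stretches of THP1 DNA were high for all 3 marks together. In 435 windows of 5 Mb with at least 15 regions, the window on chromosome 1 from 40 to 45 Mb was the highest on all 3 THP1 arrays. Its 68 regions averaged 1.09 for Pol II, 1.05 for Ser5P and 1.01 for H3K9Ac, and 0.12 ± 0.02 (SD, n = 3) for monocyte H3K4Me3. The highest regions named on chromosome 1 for the THP1 marks, and both regions with more H3K9Ac than H3K4Me3, lie in this window. Next by their lowest rank over the 3 arrays were the windows from 140 to 145 Mb, at 0.81, 0.76 and 0.73, and from 145 to 150 Mb, at 0.80, 0.85 and 0.76. In monocytes the highest windows lay on chromosome 9 from 40 to 45 Mb, at 1.03 ± 0.03, on chromosome 7 from 60 to 65 Mb, at 0.83 ± 0.03, and on chromosome 19 from 20 to 25 Mb, at 0.82 ± 0.03 (SD, n = 3). In THP1 cells these windows averaged 1.05, 0.31 and 0.36 for Pol II, 0.85, 0.51 and 0.23 for Ser5P, and 0.43, 0.07 and -0.31 for H3K9Ac.

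**Figure D4:**
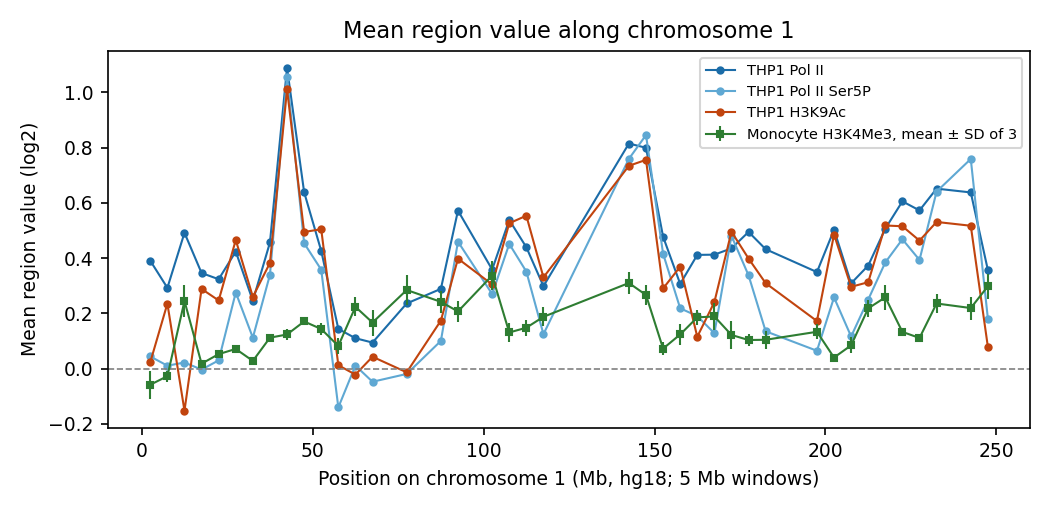
Mean region value (y axis, log2) in 5 Mb windows along chromosome 1 (x axis, hg18) for the 3 THP1 arrays, with the mean ± SD of 3 monocyte arrays. The THP1 lines reach 1.09, 1.05 and 1.01 in the window from 40 to 45 Mb, where the monocyte mean is 0.12.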

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

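The place comparison within regions and its tests were chosen after the data were seen, except the test that sets the edges of a region against each other by Ser5P, which was written before its result was known. Averaged between 600 and 1100 bp from a region edge, against the middle of the region, every THP1 polymerase array rose and every histone array fell. The differences were 0.184 for Pol II, 0.131 for Ser5P, -0.297 for H3K9Ac and -0.182 for monocyte H3K4Me3 on the log2 scale. They drew attention because the groups moved in opposite directions, and the difference between groups was not tested.

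For the histone marks the values argue against probe composition, as far as probe length and control brightness reflect it, as the whole cause, since among probes matched on both at least 84.9% of the difference was kept on each of 4 arrays (Pol II 72.3%, Ser5P 76.4%). A candidate explanation, a transcription start with fewer nucleosomes near 1 edge, predicted less H3K9Ac at the edge with more Ser5P, but H3K9Ac was higher there by 0.0516 (SE over 22 chromosomes 0.009), and by 0.042 (SE 0.032) in the top 10% of regions by Ser5P. That bound was not a fair one, because picking the edge by Ser5P also lifted the other arrays, including monocyte H3K4Me3 by 0.16, 0.14 and 0.10, each in 22 of 22 chromosomes. The dip of each edge against its flanks was tried after that result, over 12484 regions. It kept a Pol II difference of 0.32. For H3K9Ac the dip differed by -0.00057 (SE 0.009) beside a dip of -0.16. For H3K4Me3 it differed by 0.01, 0.03 and -0.01 (SE 0.010, 0.009 and 0.011), so a lift remained for volunteer 2. The H3K9Ac dip was thus about equally deep at the edges with more and with less Ser5P. Equal dips would also be seen if 1 Ser5P array did not pick the edge with the start. Neither test therefore decides on such a start. The bin from 700 bp was the lowest on every histone array, over slides 2, 3 and 4. It was at -0.09 for H3K9Ac and at -0.03, -0.002 and -0.03 for volunteers 1, 2 and 3. This argues against 1 slide as the cause of the histone dip. Both polymerase arrays lay on slide 1, so antibody and slide stay open for the difference between the groups.

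Regions on the alternative haplotype sequences of chromosome 6 entered no comparison. The means of these 273 regions lay above the level of the random-sequence probes. They were 0.315 for Pol II, 0.290 for Ser5P, 0.269 for H3K9Ac and 0.142 for monocyte H3K4Me3, against random-probe medians of -0.22, -0.63, -0.88 and a mean of -0.38. The means of the autosomal regions were 0.33, 0.12, 0.17 and 0.14, also above the random probes, so such a level is not peculiar to these sequences.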

How the results depend on the processing

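Alternatives left out chromosome 1, kept single-match probes, tested each region by its own variance or averaged arrays of a slide only after the data were seen, as were all alternatives for the place comparisons, 50 bp probes among them; the others were planned. Over 12 results and 173 comparisons with an alternative, 127 stayed within 1.5 times the count, or within the replicate SD or 95% interval of the value, 46 moved further and 0 reversed. The slide could not be fitted as a random block, since 3 arrays gave no estimate of its correlation, and averaging the arrays of a slide gave 10516 regions above and 4936 below. No paired analysis was possible because only 1 group had more than 1 array. The gene list tests and medians were not run, since regions carry no gene names. Leaving out each monocyte array gave 9498 to 10606 regions above and 4035 to 5006 below, r of 0.199 to 0.235 and shares of 25.1% to 27.8% with H3K9Ac, and r of 0.346 to 0.372 and shares of 25.7% to 27.9% with Pol II. The cause of the moves below was not tested, except where the method itself sets it. The median over probes gave 6330 regions above the median, r of 0.603, 0.428, 0.626, 0.152 and 0.258 for Pol II with Ser5P, Pol II with H3K9Ac, Ser5P with H3K9Ac, monocytes with H3K9Ac and monocytes with Pol II, and shares of 44.1%, 31.3%, 44.5% and, for monocytes with Pol II, 23.9%. The best 8 neighbouring probes gave 15972 above and 800 below, which a maximum raises by construction. Their r was 0.630 for Pol II with Ser5P, 0.636 for Ser5P with H3K9Ac and 0.362 for monocytes with H3K9Ac, with shares of 51.1%, 41.3% and 38.4%. Without dim probes r was 0.520, 0.337 and 0.617 for the THP1 pairs in that order and 0.331 for monocytes with H3K9Ac. Shares were 37.0%, 23.0% and 37.7% for the THP1 pairs and 22.7% for monocytes with Pol II. Loess gave r of 0.686 for Pol II with Ser5P and 0.466 for Pol II with H3K9Ac. The share of Pol II with H3K9Ac was 33.1% with normexp and 33.1% without chromosome 1. Single-match probes gave r of 0.327 and a share of 23.3% for monocytes with Pol II. Spearman's rho was 0.287 for monocytes with H3K9Ac. A t-test per region gave 7139 above and 2851 below. Against limma with its infinite prior, it changed both the spread used and the degrees of freedom, which fell to 2. These changes were not separated. Treat against 0.5, a stricter test by construction, gave 941 above and 0 below. Top 5% lists shared 41.2%, 28.9% and 38.8% for the THP1 pairs, 16.9% for monocytes with H3K9Ac and 19.8% with Pol II, and top 20% lists 58.6%, 46.0%, 58.6%, 39.9% and 38.4%, since the list length sets the chance level. Of 27 place comparisons 12 moved and 0 reversed. Between 16.6% and 34.6% of probes were brighter than random probes in a channel, which limits dim regions.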

Other observations

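The choice of windows, chromosomes and match counts followed the data. The tests of the low THP1 windows on the control signal and of the monocyte windows on probe length were written before their results were known, and the other tests after. Probe values rose with the number of genome places a probe matches, on all 6 arrays. Probes with 1 match averaged 0.30 for Pol II, 0.17 for H3K9Ac and 0.12 ± 0.02 (SD, n = 3) for H3K4Me3, and probes with 5 matches averaged 0.88, 0.43 and 0.75 ± 0.04. Longer regions were also higher. The 2887 regions over 4000 bp averaged 0.41 for H3K9Ac and 0.21 ± 0.03 for H3K4Me3 (SD, n = 3), against 0.12 and 0.13 ± 0.02 for the 15698 regions of 4000 bp.

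Chromosome means of monocyte H3K4Me3 ran from 0.02 ± 0.02 on chromosome 22 to 0.22 ± 0.03 on chromosome 13 (SD, n = 3). They followed mean probe length over the 22 chromosomes, with r = 0.680 (permutation p = 0.00049) and rho = 0.624 (permutation p = 0.00235), two-sided, from 100000 permutations. The relation was chosen after chromosome means and probe lengths had been looked at, so these p-values are descriptive. Without the chromosomes farthest from the median probe length r was 0.824. Chromosomes share arrays, so this describes these arrays.

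The THP1 windows high for all 3 marks, on chromosome 1 from 40 to 45, 140 to 145 and 145 to 150 Mb, were weighed for their cause. A few strongly marked promoters would leave most regions of a window low, but the 25th percentile of region values lay 3.69 SD above the mean of windows. Probes with several genome matches would leave a low mean of single-match probes. Over the THP1 arrays the windows averaged 1.05, 0.66 and 0.71 with single-match probes, against 1.05, 0.77 and 0.80 with all probes. Probes with several matches thus accounted for little of the height. The single-match mean of 0.807 lay above the 95th percentile of 0.443. Windows picked as the highest could hardly have fallen below it, so that comparison decides nothing further. DNA copy number in THP1 cells, which the control channel did not cancel, may account for the pattern: THP1 control signal minus monocyte control signal lay 4.56 SD above the mean of windows, with 8.41, 3.27 and 2.01 SD per window. A first choice of windows, with under 25% of probes of several matches, took the window from 230 to 235 Mb for that from 140 to 145 and gave 4.47 SD. It is a hypothesis found and tested on these data, and antibody, cell type and array issue differ together with it.

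For the windows low on all 3 THP1 arrays the same explanation could not be decided. The control difference averaged -1.93 SD, with -3.44 on chromosome 17 from 10 to 15 Mb, -2.43 on chromosome 9 from 20 to 25 Mb and 0.08 on chromosome 4 from 70 to 75 Mb. Over all 435 windows the THP1 mean correlated with the control difference at r = 0.635, or 0.509 without chromosome 1, and the monocyte mean at 0.036. Windows are not independent replicates.

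The monocyte windows on chromosomes 9, 7 and 19 were weighed against probe effects. After removal of the trend on probe length their mean was 0.853, above the 95th percentile of 0.272. The removal left the windows at 1.03, 0.77 and 0.75, with mean probe lengths of 53.0, 53.8 and 53.5. The trend on probe length thus accounted for little of their height. Windows picked as the highest could hardly have fallen below that percentile, so the comparison with it decides nothing further. With single-match probes the windows on chromosomes 7 and 19 were at 0.71 and 0.75, against 0.83 and 0.82 with all probes. This argues against probes with several counted matches as the main source of their height. Their single-match mean of 0.730 lay above the 95th percentile of 0.274, which decides nothing further for windows picked as the highest. The window on chromosome 9 had 0 regions with 8 single-match probes, and 92.0% of its probes had several matches, so signal and cross-matching cannot be told apart in it. No biological explanation was tested.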
